A study of Mus musculus with 4 samples.

How the data were processed

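Naive CD4+ T cells (high in CD62L, low in CD44) were sorted from spleens of male C57BL/6 mice, wild type or lacking the transcription factor Irf4, and activated with an antibody to CD3 at 1 µg per ml together with mitomycin C-treated antigen-presenting cells, with 1e+05 T cells per well. Living CD4+ cells were sorted again on day 2 and their total RNA was measured, per the labels. A treatment protocol among the labels names shorter cultures than the 2 days of the design text, and the day 2 of the design text and titles was taken. Each genotype has 2 samples, and the labels state that 2 independent experiments were run.

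Each sample was hybridised to 1 one-colour (Cy3) Agilent mouse gene expression array with 62976 spots. Per the file headers, the authors scanned the arrays and extracted spot intensity with Agilent Feature Extraction 11.0.1.1, whereas the submitters' processing notes name version 9.1. The deposited intensity used here is the processed signal, from which the extraction software had subtracted background with a spatial trend, per the file headers. It had not been normalized between arrays. The authors also deposited a table of log2 values. Set against the scanner files, each of its columns equalled log2 of the processed signal less the array's 75th percentile, up to a constant shift of at most 0.03, and each probe was centred on its mean over the 4 arrays. Its column medians were -0.17 and 0.10 for the wild-type arrays and -0.11 and 0.12 for the knockout arrays. Centring removed the level of each probe, so the table served only as an alternative source of differences.

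All 4 arrays lay on 1 slide and were scanned once, so neither slide nor scan could act as a batch. Replicate 1 of both genotypes lay in slide row 1 and replicate 2 of both in row 2. The lowest signal counted as well above background was 12.0 and 11.7 in row 1 against 18.3 and 19.9 in row 2. Row and replicate number therefore coincide, and 1 fit with this factor as a block stands for both. Both wild-type arrays lay in slide column 1, and knockout replicates 1 and 2 in columns 3 and 2. An effect of slide column therefore cannot be told apart from genotype. Deviations from the group means of same-numbered arrays correlated at r = 0.348 across genes, but nothing in the labels says that a number marks a shared experiment, and with 2 pairs this does not establish pairing.

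Control spots and spots with outlier or manual flags were left out, and spots of 1 probe were averaged as log2 values. Of 56605 non-control probes, 137 had no unflagged spot on some array. The scanner files give accessions and no gene symbols. Accessions of 32994 probes matched 22911 symbols in a RefSeq table of assembly GRCm38.p6, and 23611 probes kept the name in the file. The array design was built on mm9, so no coordinates are given and the table served for names and for the order of neighbouring genes. The main values were log2 of the processed signal minus each array's 75th percentile over non-control spots. A gene with several probes was represented by the one with the highest mean log2 signal over all 4 arrays. Of 45526 genes or unnamed transcripts, 20505 whose probe was well above background on both arrays of at least 1 genotype were tested, 12912 of them with a symbol.

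Knockout and wild-type arrays were compared with limma 3.58.1 (lmFit and eBayes without trend) in R 4.3.3, with Benjamini-Hochberg adjustment over all 20505 and a threshold of 0.05. Errors beside log2 fold changes are limma's moderated standard errors (SE), from 2 residual and 2.95 prior degrees of freedom. Where no probe of a gene was well above background on either array of 1 genotype, its fold is a lower bound, written "at least". The bound sets the brighter genotype's mean against the dimmer one's mean of, per array, the lowest signal well above background or the probe's own signal if higher. Gene lists were tested as sets with camera, with a preset inter-gene correlation of 0.01, over 28 lists with at least 5 tested members. With the preset correlation camera compares genes with genes, so its p does not measure the spread between arrays. List calls are given with the adjusted p of camera when the correlation was estimated from the data. That version rests on the 2 residual degrees of freedom, and its smallest adjusted p over the 28 lists was 0.588. It had little power here, so a list it did not call is not shown to be unchanged. The 29 lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined, apart from the alternatives said to be added.

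The rule named Irf4, the 12 largest increases and the 12 largest decreases past the threshold with both knockout arrays beyond both wild-type arrays, a regular symbol and signal above background on every array. It added the 4 largest bounds per direction among genes above background in 1 genotype only, up to 4 members of each list past the threshold, and list members given as not passing, which were picked after their values were seen. A few further genes, said to be so, were also chosen after their values were seen. The inhibitory receptor list holds genes that this study is known to report on, so it is not independent of the study. Some list members are not reported here singly.

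Alternatives were quantile normalization, scaling on the array median, normexp background correction (offset 50), no filter on dim probes, signal above background on all 4 arrays, the mean of a gene's probes, eBayes with trend and robust settings, the block on replicate number, the deposited table, each array left out in turn, other thresholds, and an estimated inter-gene correlation. The files lack the mean spot signal, so normexp used the median spot signal and the median local background. Scaling on the 75th percentile of probes detected on all 4 arrays was added after seeing the data. Trend and robust settings do not enter camera, so that setting could not alter a list call, though it is among the settings counted for lists. The test was checked on simulated data with the spread of the 20505 tested genes: it recovered 0.800% of genes changed 2-fold, 58.6% of those changed 4-fold, 87.2% of those changed 8-fold and 93.7% of those changed 16-fold, and 4.98% of its calls were false. The simulated errors were independent and drawn from limma's own fitted spread, without the deviations that same-numbered arrays share. A false share near the threshold was therefore built in and does not measure that of the real calls. The number of arrays limits the precision. Between 45.4% and 50.9% of probes were well above background on an array, and no probe was saturated. The 4 tested Y-linked genes were above background on all arrays and Xist on none, in keeping with the male label.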

Results

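Transcript levels were measured on 4 one-colour arrays in CD4+ T cells 2 days after activation, 2 arrays from wild-type mice and 2 from mice lacking Irf4, a transcription factor that activated T cells induce through their antigen receptor. The comparison asks how the expression programme of newly activated helper T cells differs without Irf4. Between 25710 and 28784 of 56605 probes were well above background on an array, and 20505 genes or unnamed transcripts were tested. Arrays of 1 genotype correlated at r = 0.992 (wild type) and r = 0.989 (knockout) across these genes, which are not independent replicates, and arrays of different genotypes at r = 0.978 to 0.986. Levels are log2 signals relative to the array's 75th percentile, with n = 2 arrays per genotype throughout.

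The targeted gene was read first. Irf4 signal was 4.89 ± 0.20 (SD) in wild-type cells and 4.14 ± 0.14 in knockout cells, a log2 difference of -0.75 ± 0.20 (SE) that did not pass the test (limma, adjusted p = 0.231). Both knockout arrays lay below both wild-type arrays, by 0.80 in slide row 1 and 0.70 in row 2. The difference passed with trend and robust settings (adjusted p = 0.0258) and with normexp (adjusted p = 0.0267), and a second Irf4 probe differed by -0.37. Where these probes lie relative to the deleted part of the gene is not given in the sources used here, so the signal left in the knockout arrays checks nothing about the deletion.

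Cells lacking Irf4 had higher signal for 101 genes or transcripts and lower signal for 50 at an adjusted p under 0.05 (limma), and 80 of the former and 43 of the latter carried a symbol. Among those above background on every array, the median change was 4.44-fold for 60 that rose and 4.52-fold for 26 that fell, and the smallest was 2.84-fold. All 151 moved the same way in both slide rows, which their selection on these same arrays nearly ensures, so it is no separate evidence. The number of calls depended on the setting, from 0 to 1042 (median scaling, whose anchor lay near the limit of background). With replicate number, which equals slide row, as a block limma called 0 genes (3195 at an unadjusted p under 0.05, against 2331 without the block). It also called 0 without wild-type replicate 1 (1864 unadjusted) or wild-type replicate 2 (1678 unadjusted), and 487 without knockout replicate 1.

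Among genes with a symbol that passed the test and were above background on every array, the largest increase was that of Csf2, which encodes the cytokine GM-CSF, at 24.4-fold (log2 4.61 ± 0.39 SE, adjusted p = 0.0318). Ikzf2, encoding the Ikaros-family transcription factor Helios, rose 15.2-fold (adjusted p = 0.0392). Among surface receptors of activated and cytotoxic lymphocytes, Crtam rose 13.1-fold (adjusted p = 0.0309) and the co-receptor gene Cd160 10.7-fold (adjusted p = 0.0395). Bdh2, a short-chain dehydrogenase gene, rose 14.6-fold and the microtubule-associated Map2 12.3-fold. The remaining genes among the 12 largest increases were Wdfy1 (10.3-fold), Ccdc184 (10.1-fold), the ubiquitin ligase subunit gene Asb2 (9.07-fold), Srgap3 (8.36-fold), the amino acid transporter gene Slc43a1 (8.27-fold) and Atp8b4 (8.17-fold). Adjusted p lay between 0.0293 and 0.0402 for all 12. Other genes were well above background on both knockout arrays and on neither wild-type array. Signal was at least 43.8-fold higher for Oasl2, an interferon-induced oligoadenylate synthetase-like gene, at least 13.1-fold higher for Sh3bgrl2, at least 11.9-fold higher for the chemokine gene Xcl1 and at least 10.2-fold higher for the cytokine gene Il31. Levels on knockout replicates 1 and 2 were 0.17 and 1.85 for Oasl2 and -1.39 and -0.08 for Sh3bgrl2. They were -1.32 and -0.43 for Xcl1 and -1.38 and -0.80 for Il31. Each of these bounds would therefore be smaller without knockout replicate 2.

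**Figure D1:**
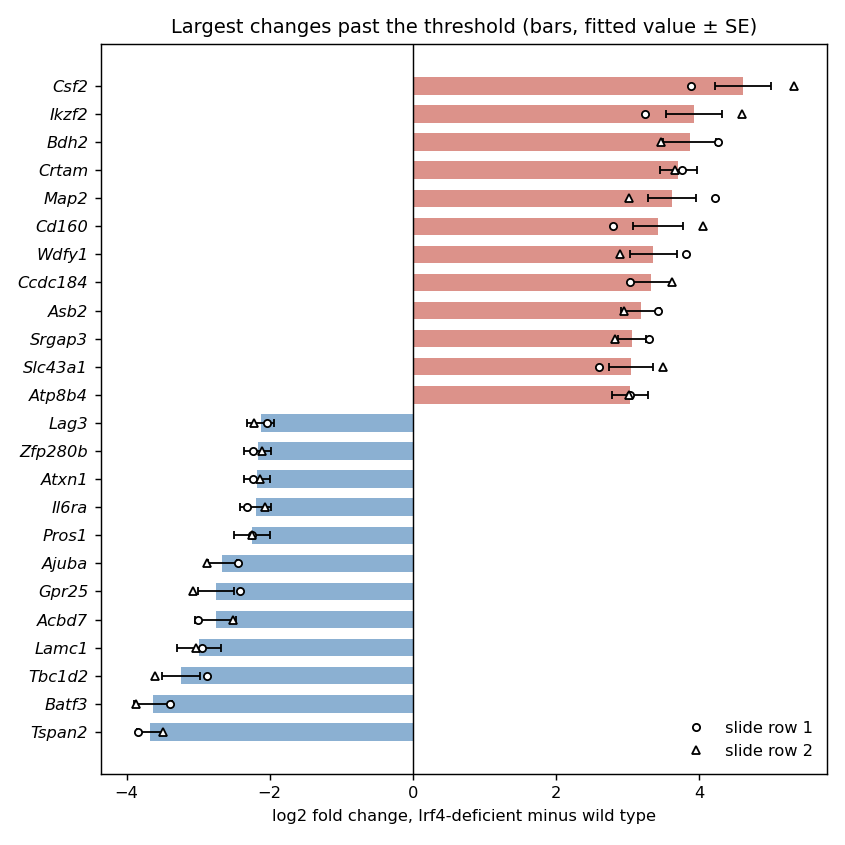
Log2 fold change (Irf4-deficient minus wild type, x axis) of the 12 genes with the largest increase and the 12 with the largest decrease past the threshold; bars show the fitted value, error bars its SE, and open symbols the difference within each slide row. The symbols of each gene lie on the same side of 0, as the rule that chose the genes requires. Fitted values run from Csf2 at 4.61 to Tspan2 at -3.67.

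The tetraspanin gene Tspan2 fell 12.7-fold (log2 -3.67 ± 0.18 SE, adjusted p = 0.0293). Batf3, whose product belongs to the basic leucine zipper family that binds DNA together with Irf4, fell 12.4-fold (log2 -3.63 ± 0.26 SE, adjusted p = 0.0318). They were followed by the Rab GTPase-activating Tbc1d2 (9.44-fold), the laminin subunit gene Lamc1 (7.95-fold), Acbd7 (6.75-fold), the orphan receptor gene Gpr25 (6.72-fold) and the LIM-domain scaffold gene Ajuba (6.32-fold). Smaller decreases were those of Pros1, which encodes protein S (4.75-fold), the interleukin 6 receptor gene Il6ra (4.58-fold), Atxn1 (4.54-fold), Zfp280b (4.49-fold) and the inhibitory receptor gene Lag3 (4.37-fold). Adjusted p lay between 0.0293 and 0.0486 for all 12. Signal well above background in wild-type cells and not in knockout cells was at least 12.8-fold lower for Wnt10a, at least 12.7-fold lower for the purinergic receptor gene P2ry1, at least 12.5-fold lower for the matricellular gene Ccn4 and at least 12.2-fold lower for the protease gene Tmprss13. Levels on wild-type replicates 1 and 2 were 0.07 and -1.31 for Wnt10a and -0.18 and -1.08 for P2ry1. Both bounds would be smaller without wild-type replicate 1, and that of Wnt10a would not be the largest.

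Inhibitory receptor and dysfunction genes went both ways. Of 26 tested members 3 rose, Lag3 fell and 22 did not pass. Those that rose were Ikzf2, Cd160 and the ectonucleotidase gene Nt5e (3.76-fold, adjusted p = 0.0443). Adjusted over the list alone, 9 were higher and 4 lower, but the list holds genes the study is known to report on and is not independent evidence. Pdcd1, encoding PD-1, was 3.42-fold higher (log2 1.77 ± 0.23 SE) without passing the test over all genes (adjusted p = 0.0599), and higher by 1.53 and 2.02 in the 2 slide rows. The nuclear receptor gene Nr4a2 (log2 difference 1.90, adjusted p = 0.0717) and Tox (1.60, adjusted p = 0.151) also did not pass. Neither did the inhibitory receptor genes Btla (-1.30, adjusted p = 0.0666) and Ctla4 (-0.93, adjusted p = 0.263). As a set the list was not called (camera, adjusted p = 0.200), except with median scaling (adjusted p = 0.00528, the range over all settings being 0.00528 to 0.659); its median was -0.04, its mean 0.40 and its test direction up.

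**Figure D2:**
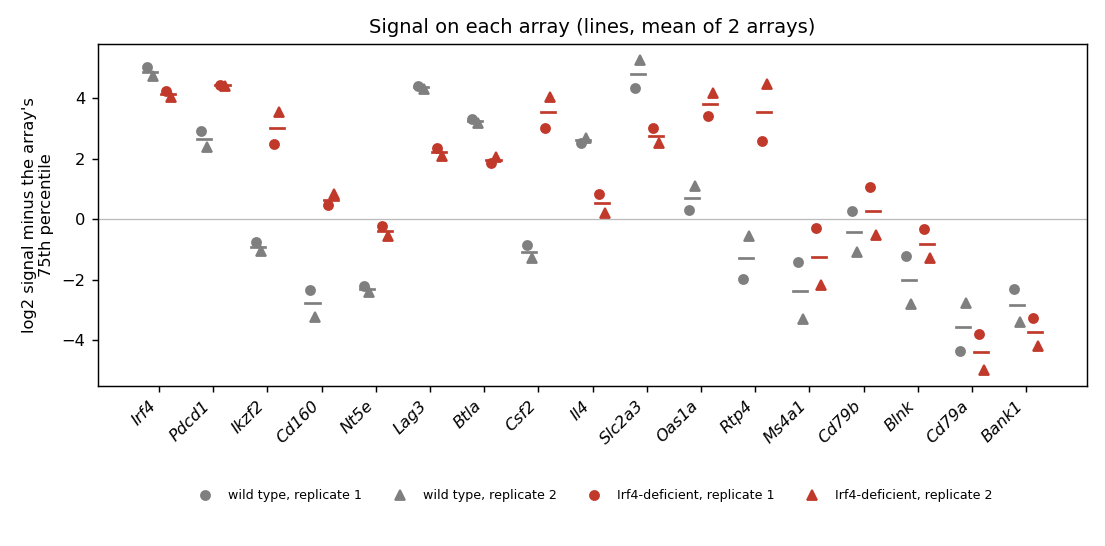
Log2 signal minus the array's 75th percentile (y axis) of selected genes on each of the 4 arrays; horizontal lines are the means of 2 arrays. Pdcd1, Ikzf2, Cd160, Nt5e and Csf2 lie higher on both knockout arrays, Lag3 and Btla lower, and among B-cell markers Ms4a1, Cd79b and Blnk have higher means in the knockout while Cd79a and Bank1 have lower ones.

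Cytokine genes were divided too. Of 20 effector cytokine genes tested, Csf2 alone passed over all genes and 19 did not, while adjusted over the list alone 7 were higher and 4 lower. Il4 differed by -2.08 (adjusted p = 0.0561), Il2 by -0.98 (adjusted p = 0.133) and Ifng by 0.48 (adjusted p = 0.449). Il17a was not well above background in the knockout and at least 3.67-fold lower (adjusted p = 0.110). The brightest Il21 probe was below background on both knockout arrays while a second probe differed by -0.43, so Il21 gave no settled value. The set as a whole was not called (median 0.54, camera adjusted p = 0.0573; adjusted p = 0.588 with an estimated correlation). It was called higher in 10 of 15 settings, among them the block (adjusted p = 0.0460) and leaving out wild-type replicate 1 (0.0241) or knockout replicate 1 (0.0271), with adjusted p from 0.00171 to 0.588 over all settings.

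Genes of killer-cell function, activation receptors and chemokines were called higher as sets with the preset correlation, and none of the 3 sets with an estimated one (adjusted p = 0.588, 0.588 and 0.659). The B-cell and myeloid marker sets were called higher too (medians 0.96 and 0.32; adjusted p = 0.588 for both with an estimated correlation), and both the chemokine and the B-cell call were lost without knockout replicate 1 (adjusted p = 0.447 and 0.0579). Of 10 cytotoxic molecule genes tested, Nkg7 (7.25-fold, adjusted p = 0.0493) and Tnfsf10, which encodes the death ligand TRAIL (4.45-fold, adjusted p = 0.0456), rose and 8 did not pass. Adjusted over the list alone 3 were higher and 1 lower. The granzyme B inhibitor gene Serpinb9 differed by 1.76 (adjusted p = 0.0510) and Gzma by -2.19 (adjusted p = 0.230), or -1.33 without wild-type replicate 2. The list's median was 0.41 (0.49 and 0.52 in slide rows 1 and 2; camera adjusted p = 0.00605; adjusted p = 0.588 with an estimated correlation). It was not called without knockout replicate 2 (adjusted p = 0.0713) or wild-type replicate 1 (adjusted p = 0.185). Among 19 activation receptor genes, the costimulatory receptor gene Tnfrsf9 (4-1BB) rose 3.75-fold (adjusted p = 0.0487) and 18 did not pass, with 6 higher and 1 lower adjusted over the list alone. Cd83 differed by 2.46 (adjusted p = 0.122), Cd44 by 0.76 (adjusted p = 0.166) and Il2ra, the interleukin 2 receptor alpha chain gene, by -0.14 (adjusted p = 0.928), spanning -0.28 (without knockout replicate 2) to near 0 (without knockout replicate 1) when 1 array was left out. This set's median was 0.40 (0.36 and 0.39 by row; camera adjusted p = 0.00531; adjusted p = 0.588 with an estimated correlation). Of 16 chemokine and chemokine receptor genes, Xcl1 rose and 15 did not pass, with 5 higher and 3 lower adjusted over the list alone. Ccr8 differed by 1.51 (adjusted p = 0.0543), Ccr4 by -1.57 (adjusted p = 0.0837), Ccr6 by -1.97 (adjusted p = 0.209; -1.27 without knockout replicate 2) and Cxcl10, above background on 1 of 2 wild-type arrays, by 3.06 (adjusted p = 0.0600). Its median was 0.37 (0.43 and 0.14 by row; camera adjusted p = 0.0475; adjusted p = 0.659 with an estimated correlation). The call was lost in 7 of 15 settings, among them leaving out knockout replicate 1 or wild-type replicate 2. It was also lost with only the 13 members above background on all 4 arrays (camera adjusted p = 0.727), which leaves out Xcl1.

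The type I interferon response had the largest median shift of the 28 lists. All 22 tested members had positive differences, 19 of them in both slide rows, with a median of 1.58 (1.19 and 1.93 in slide rows 1 and 2; camera adjusted p = 7.64e-13; adjusted p = 0.588 with an estimated correlation). Limma's fry, which tests a list against the spread of the arrays and is not among the alternatives listed above, gave an unadjusted p of 0.117. Over the lists called by camera, fry p ran from 0.00199 (activation receptors) to 0.342 (mitosis). Oasl2 passed over all genes and 21 did not. Adjusted over the list alone 11 were higher. Rtp4 differed by 4.81 ± 0.76 (SE, adjusted p = 0.0839), Oas1a by 3.10 (adjusted p = 0.0561), Oas2 by 3.51 (adjusted p = 0.260) and Ifit3 by 2.75 (adjusted p = 0.260). Isg15 differed by 1.60 (adjusted p = 0.411). Irf7, an interferon-induced regulator in another list, differed by 2.12 (adjusted p = 0.289). The knockout arrays themselves lay apart, with SDs of 1.33 for Rtp4 and 2.09 for Oas2 (1.00 and 0.57 in wild type). Without knockout replicate 2 the differences were 2.03 for Oas2, 1.59 for Ifit3, 0.76 for Isg15 and 1.37 for Irf7. In both genotypes these genes and Rtp4 were higher in slide row 2, so leaving out 1 array mixes the row gap into the difference. Within rows 1 and 2 the differences were 2.44 and 4.59 for Oas2, 1.87 and 3.63 for Ifit3, and 1.09 and 2.12 for Isg15. They were 1.97 and 2.27 for Irf7 and 4.58 and 5.04 for Rtp4. The B-cell and myeloid marker sets were also called higher (medians 0.96 and 0.32; adjusted p = 0.588 for both with an estimated correlation).

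**Figure D3:**
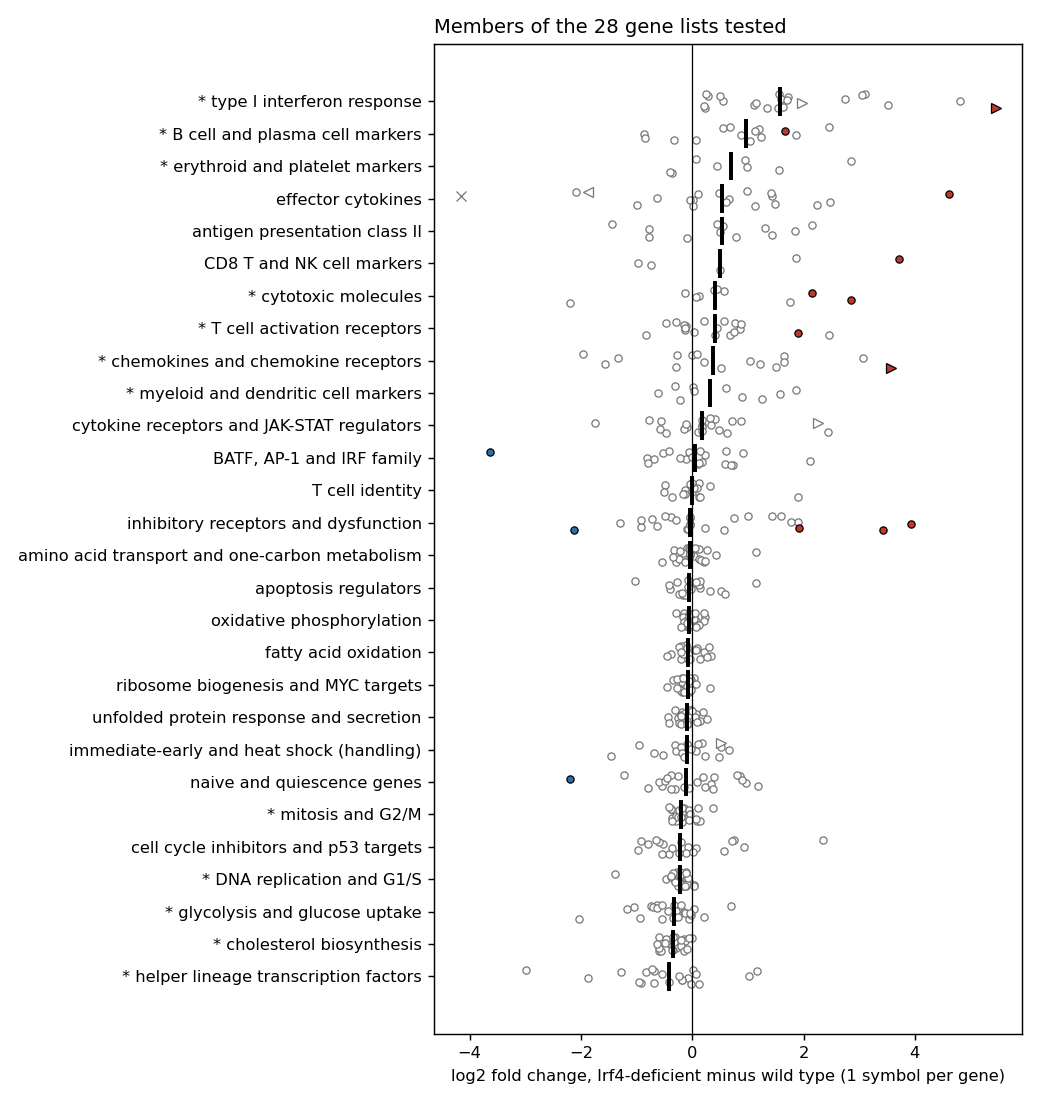
Log2 fold change (Irf4-deficient minus wild type, x axis) of every tested member of 28 gene lists (y axis, ordered by median); filled symbols passed the test over all genes, triangles are lower bounds for genes below background in 1 genotype, the cross is Il21, whose probe was below background in the knockout, vertical bars are list medians and asterisks mark lists called by camera with the preset correlation. Medians run from 1.58 for the interferon response to -0.42 for helper lineage transcription factors.

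Genes of cholesterol synthesis, glucose use, helper lineage regulation and the cell cycle were called lower as sets with the preset correlation. None of these sets was called by camera with an estimated one (adjusted p = 0.588 to 0.877). In cholesterol biosynthesis 22 of 23 tested genes had negative differences, 21 of them in both slide rows, with a median of -0.34 (-0.24 and -0.39 by row; camera adjusted p = 8.45e-06; adjusted p = 0.588 with an estimated correlation). None passed singly over all genes or adjusted over the list alone. Pmvk differed by -0.64 (adjusted p = 0.244) and Lss by -0.60 (adjusted p = 0.311). Of 25 glycolysis and glucose uptake genes, 22 had negative differences (median -0.32; -0.20 and -0.40 by row; camera adjusted p = 3.60e-05; adjusted p = 0.588 with an estimated correlation). None passed over all genes, and 2 were lower adjusted over the list alone. The glucose transporter gene Slc2a3 differed by -2.04 (adjusted p = 0.117) and the hexokinase gene Hk2 by -1.18 (adjusted p = 0.0839), while the transporter gene Slc2a1 differed by -0.63 (adjusted p = 0.270). Among 21 helper lineage transcription factor genes, 16 were negative (median -0.42; -0.42 and -0.64 by row; camera adjusted p = 0.00106; adjusted p = 0.588 with an estimated correlation). None passed over all genes and 4 were lower adjusted over the list alone. Tbx21, encoding T-bet, differed by -0.96 (adjusted p = 0.117), Maf, above background on 1 of 2 knockout arrays, by -2.99 (adjusted p = 0.144), and Prdm1, encoding Blimp-1, by -1.88 ± 0.81 (SE, adjusted p = 0.506). The Prdm1 difference was -0.73 and -3.03 by row and -0.63 without wild-type replicate 2.

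Of 30 genes of DNA replication and the G1/S transition, 28 had negative differences (median -0.22; -0.29 and -0.16 by row; camera adjusted p = 0.00106; adjusted p = 0.838 with an estimated correlation). Over all genes none passed, and 1 was lower adjusted over the list alone. That gene, the cyclin gene Ccne2, above background on 1 of 2 knockout arrays, differed by -1.38 (adjusted p = 0.0811), and Ccne1 by -0.48 (adjusted p = 0.397). Of 28 mitosis genes 23 were negative and none passed over all genes or adjusted over the list alone (median -0.20; -0.33 and -0.06 by row; camera adjusted p = 0.0205; adjusted p = 0.877 with an estimated correlation), with Mki67 at -0.42 (adjusted p = 0.530), or -0.28 without wild-type replicate 1. The G1/S call was lost without wild-type replicate 1 (adjusted p = 0.558) or knockout replicate 2 (adjusted p = 0.0788), and the mitosis call without wild-type replicate 1 (adjusted p = 0.810), without knockout replicate 1 (adjusted p = 0.232) and with median scaling (adjusted p = 0.229).

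Marker lists of B cells, myeloid cells and erythroid cells and platelets were called higher with the preset correlation, and none of these with an estimated one (adjusted p = 0.588 for each). Of 14 B-cell marker genes tested, Fcmr rose 3.18-fold (adjusted p = 0.0395) and 13 did not pass, with 4 higher adjusted over the list alone. Differences were positive for 11 and negative for 3. The median was 0.96 (0.84 and 0.96 by row; camera adjusted p = 4.95e-04; adjusted p = 0.588 with an estimated correlation; adjusted p = 0.0579 without knockout replicate 1). Pou2af1 differed by 2.46 (adjusted p = 0.0684), Cd72 by 1.87 (adjusted p = 0.0981), Blnk by 1.19, Ms4a1 by 1.13 and Cd79b by 0.68, the last 3 with adjusted p between 0.604 and 0.877. Without knockout replicate 1 the Cd79b difference turned to -0.12. Leaving out 1 array moved Ms4a1 to between 0.18 (without wild-type replicate 2) and 2.08 (without wild-type replicate 1), and Blnk to between 0.40 and 1.99 (without the same arrays). In both genotypes these 3 genes were higher in slide row 1, so leaving out 1 array mixes the row gap into the difference. Within rows 1 and 2 the differences were 1.11 and 1.15 for Ms4a1, 0.80 and 0.57 for Cd79b, and 0.88 and 1.51 for Blnk. Cd79a (-0.84), Bank1 (-0.87) and Cr2 (-0.33), each above background on 1 of 2 knockout arrays, were the negative ones, with adjusted p between 0.644 and 0.904. Leaving out 1 array moved Cd79a to between -1.64 (without wild-type replicate 1) and -0.05 (without wild-type replicate 2), Bank1 to between -1.42 (without wild-type replicate 2) and -0.33 (without wild-type replicate 1), and Cr2 to between -0.87 and 0.21 (without knockout replicates 1 and 2). Of 10 myeloid marker genes none passed over all genes and 5 were higher adjusted over the list alone, among them Tyrobp (1.87, adjusted p = 0.0650) and Ctss (1.57, adjusted p = 0.0539). That set's median was 0.32 (0.24 and 0.29 by row; camera adjusted p = 0.0246; adjusted p = 0.588 with an estimated correlation). Adjusted p was 0.0671 with the block, 0.0577 without knockout replicate 1 and 0.0877 without the filter on dim probes. The 8 erythroid and platelet genes, none of which passed over all genes or adjusted over the list alone, had a median of 0.69 (0.28 and 1.13 by row; camera adjusted p = 0.0475; adjusted p = 0.588 with an estimated correlation), with Hba-a1 at 0.95 (adjusted p = 0.591), or 0.26 without knockout replicate 2. Their call was lost in 9 of 15 settings, with adjusted p = 0.106 with the block, 0.143 without wild-type replicate 2 and 0.0788 without knockout replicate 2. The 12 class II antigen presentation genes were not called (median 0.53, camera adjusted p = 0.223; none passed over all genes, 2 higher and 1 lower adjusted over the list alone): H2-Ab1 differed by -1.44 (adjusted p = 0.174) and Cd86 by 2.15 (adjusted p = 0.138). This set was called higher with the block (adjusted p = 0.0460), with median scaling (0.0122) and without wild-type replicate 1 (0.0118), with adjusted p up to 0.838 over all settings.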

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

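All alternatives were chosen before the data were examined except scaling on the 75th percentile of probes detected on all arrays. Against 101 genes higher and 50 lower, counts of 0 and 0 came from an adjusted p under 0.01, from no filter on dim probes, from the added scaling and from the replicate block, and quantile normalization gave 3 and 2. The same 0 and 0 came without either wild-type array, and leaving out each array in turn spanned 0 to 331 higher and 0 to 156 lower. Counts rose to 486 and 311 with trend and robust settings, 594 and 448 with median scaling, 461 and 299 with normexp and 179 and 81 with the authors' deposited values. With every array kept and 20505 genes tested, 2152 (median scaling) to 3195 (replicate block) reached an unadjusted p under 0.05 (limma). By chance 1025 would be expected. Requiring signal above background on every array gave 2015 of 18563 tested. Without the filter on dim probes it was 2099 of 45526, a share below the 0.05 expected by chance. The smallest adjusted p at the main setting was 0.0293 (limma). The prior degrees of freedom ran from 2.08 with quantile normalization to 10.4 with normexp, with no finite value for median scaling; the cause was not tested. Median scaling moved the median of all genes from -0.02 to -0.13. Its anchor, the median spot signal, was 16.8 to 18.6 over the arrays, near the lowest signal well above background (11.7 to 19.9).

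The Irf4 difference passed the test with trend and robust settings (-0.75, adjusted p = 0.0258) and with normexp (-0.72, adjusted p = 0.0267) and in no other setting; without 1 array it spanned -0.89 to -0.60. Against 7 lists higher and 5 lower, an estimated correlation gave 0 and 0, with 1 list at an unadjusted p under 0.05 (cholesterol biosynthesis, p = 0.0384), and median scaling gave 11 higher. With 2 residual degrees of freedom the estimated correlation left little power, so its 0 and 0 does not decide against the calls. Leaving out an array spanned 5 to 8 lists higher and 3 to 7 lower, and the block gave 8 and 5, 10 of them among the 12 called without it. Of single genes, the Cd79b and Cr2 differences reversed: with 1 array left out Cd79b spanned -0.12 (without knockout replicate 1) to 1.49 and Cr2 -0.87 to 0.21 (without knockout replicate 2), and Cr2 was 0.51 with the mean of its probes. Within slide rows 1 and 2 the differences were 0.80 and 0.57 for Cd79b and 0.25 and -0.91 for Cr2. Slide or scan as a block was not run, since all arrays share both. With 1 array left out, the lone array of a genotype is assumed to vary like the other pair. Signal over background limits 33 of the called genes in wild-type cells and 16 in knockout cells, whose changes are bounds.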

Other observations

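The interferon test, the B-cell test and the genes named singly in this part were chosen after the values were seen, while the tests on neighbours of Irf4 were set beforehand. Among genes outside the lists, Penk, which encodes the opioid precursor proenkephalin, was higher in the knockout (log2 2.80, adjusted p = 0.0456), as were Jdp2, a repressor of AP-1 (2.45, adjusted p = 0.0465), Lrrc32, whose product GARP anchors latent TGF-beta (1.79, adjusted p = 0.0428), and the interferon-induced Ifi27 (2.62, adjusted p = 0.0318). Zeb2, a regulator of terminal differentiation in killer cells, was above background on 1 of 2 wild-type arrays and higher in the knockout by 2.27 (adjusted p = 0.0318). Of the interleukin 18 receptor genes, Il18r1 differed by 2.45 (adjusted p = 0.136) and Il18rap, below background in wild-type cells, by at least 4.81-fold (adjusted p = 0.0706). The 23 cytokine receptor and JAK-STAT genes held no gene past the threshold over all genes and 2 higher adjusted over the list alone, and the set was not called (median 0.18, camera adjusted p = 0.0573; adjusted p = 0.588 with an estimated correlation). It was called higher with the block (adjusted p = 0.0385), quantile normalization (0.0310) and normexp (0.0340) and without wild-type replicate 2 (0.0480).

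In the BATF, AP-1 and IRF family Batf3 fell and 21 of 22 genes did not pass, with Batf at 0.91 (adjusted p = 0.165; median 0.05, camera adjusted p = 0.967; 1 higher and 3 lower adjusted over the list alone); the mean was -0.04 and the test direction down. Of 24 naive and quiescence genes Il6ra fell and 23 did not pass, with Il7r at -0.80 (adjusted p = 0.157; median -0.11, camera adjusted p = 0.804; 4 higher and 3 lower adjusted over the list alone). Of 5 genes of CD8 T and NK cells Crtam rose while Cd8b1 differed by -0.98 (adjusted p = 0.0979; median 0.50, camera adjusted p = 0.335, and 0.00316 with median scaling; 2 higher and 2 lower adjusted over the list alone). No gene passed over all genes in any of the other lists, and none of these was called at the main setting. Cell cycle inhibitors and p53 targets had a median of -0.22 (camera adjusted p = 0.335; 4 higher and 3 lower adjusted over the list alone), with Cdkn2a at 2.36 (adjusted p = 0.0781). Immediate-early and heat shock genes had a median of -0.10 (camera adjusted p = 0.738; 1 higher and 1 lower adjusted over the list alone), with the heme oxygenase gene Hmox1 at -1.46 (adjusted p = 0.0764). T cell identity genes had a median of -0.01, a mean of 0.05 and a test direction down (camera adjusted p = 0.967; 1 higher adjusted over the list alone). The following had 0 genes past the threshold adjusted over the list alone: oxidative phosphorylation (median -0.05, camera adjusted p = 0.962), fatty acid oxidation (-0.07, adjusted p = 0.804), amino acid transport and one-carbon metabolism (-0.04, adjusted p = 0.967), ribosome biogenesis and MYC targets (-0.08, adjusted p = 0.190), the unfolded protein response (-0.09, adjusted p = 0.258) and apoptosis regulators (-0.05, adjusted p = 0.967). Against these negative medians, the means of the amino acid and apoptosis lists were slightly above 0, and the apoptosis test pointed up. The ribosome list was called lower with normexp (adjusted p = 0.0247), without the filter on dim probes (0.0371) and without wild-type replicate 2 (0.00579), and without wild-type replicate 1 its test pointed up (0.807). Oxidative phosphorylation was called lower without wild-type replicate 2 (adjusted p = 0.0394), and its test pointed up without wild-type replicate 1 (0.128) or knockout replicate 2 (0.566). The 4 tested sex-linked genes were too few for a set test and none passed (median -0.06).

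The interferon response genes were higher in the knockout, and the signal was larger on knockout replicate 2. That array alone did not carry the shift, since the median was 1.19 in slide row 1, which lacks it, and camera with the preset correlation called the list without it (p = 1.3e-10), although with an estimated correlation the list was not called on all arrays (adjusted p = 0.588). The B-cell marker list was called higher too (median 0.96; adjusted p = 0.588 with an estimated correlation), and whether carried-over B cells brought interferon-induced transcripts was not tested and stays open. A direct effect of the missing Irf4, a response to interferon made by other cells in the well, and a difference between the culture wells also stay open.

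The sort kept living CD4+ cells, yet B-cell markers were measured in both genotypes, Cd79b at -0.41 in wild type and 0.27 in the knockout. Of the 14 tested, 10 were higher in the knockout in both slide rows, while Bank1 was lower in both and 3 others, Cd79a and Cr2 among them, were higher in row 1 and lower in row 2. Between the knockout arrays Fcmr differed by -0.05, Pou2af1 by 0.35 and Cd72 by 0.86, within the range of the other markers (-0.69 to 1.86). Residual B-cell RNA and expression by the T cells cannot be told apart for these genes, because the markers do not move together and there are 2 arrays per genotype. Fcmr and Pou2af1 are known in T cells as well.

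Mice made from stem cells of another strain can keep that strain's DNA around the targeted gene, which could shift signals of neighbouring genes. Only 4.07% of called genes with a known place lay among the 200 tested genes nearest to Irf4, so this does not account for the calls as a whole. Among those neighbours 5 were called (2.50%) against 0.928% of other genes (one-sided Fisher exact p = 0.0424). Serpinb6b, Gm6093, 1110046J04Rik, Nid1 and Atxn1 may therefore owe their differences (log2 1.89 for Serpinb6b and -2.18 for Atxn1, and at least 3.91-fold, 3.07-fold and 2.10-fold higher for Gm6093, 1110046J04Rik and Nid1) to retained donor DNA, or to a local effect of the deletion. Counted in tested genes from Irf4, Serpinb6b lay at 6, Gm6093 at 8 and 1110046J04Rik at 11, but Atxn1 at 56 and Nid1 at -89. Either account is thus less direct for the last 2. The labels name C57BL/6 alone, and strain sequences were not used here.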
